A study of Cicer arietinum with 8 samples.

How the data were processed

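Total RNA from leaves of chickpea (*Cicer arietinum*, variety PUSA 372) was hybridised to 8 arrays on 1 slide. There were 3 arrays of mock-sprayed plants, 3 of plants taken 24 h after spraying with spores of the fungus *Alternaria brassicae* (24 hpi) and 2 of plants taken 48 h after it (48 hpi). Per the labels, plants were 25 days old and the samples are numbered as biological replicates. The labels do not say whether each replicate came from a separate batch of plants, so p-values measure the spread between these samples. They do not state when mock leaves were harvested, and they call the treatment spraying in some fields and infiltration in others. The mock group was used as 1 reference for both times.

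The deposited scanner files hold an intensity per spot. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1, which subtracted a fitted background surface, removed a spatial trend and gave dim spots surrogate values. The deposited value table of the series holds log2 values. Each of its columns equalled the log2 processed intensity of that array minus its 75th percentile, up to a constant between -0.00377 and -0.00126, so scale, centring and direction were all recovered. Its column medians were -2.87, -2.80 and -3.02 for mock, -3.02, -2.82 and -3.00 at 24 hpi, and -3.10 and -3.10 at 48 hpi. It served as an alternative to the scanner values.

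The processed intensities were taken to log2 and each array's 75th percentile over non-control probes was subtracted. Spots marked as non-uniform by the scanner software were set to missing, and control spots were left out. The probes belong to 39613 contigs (assembled transcript sequences), 20275 of them with several probes. A contig was represented by its probe with the highest mean over all arrays. It entered the fit where that probe was well above background on every array of at least 1 group, which left 26160 contigs. Each comparison tested contigs with at least 2 unmarked arrays in both groups. This rule was added after contigs with 1 unmarked array in a group had been seen among the largest changes.

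Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 arrays with no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p of a contig is from limma. Where no probe of a contig was well above background on any array of a group, the fold is given as a bound, worded as at least. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the contig's own value and the lowest log2 value well above background there. That lowest value is the dimmest spot that was seen, and not a limit of detection for each spot. The bound is therefore approximate. The number of arrays limits the precision.

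All probe descriptions in the files read as unknown, and 0 contig names occurred among the 29938 genes of the reference table for assembly Cicar.CDCFrontier_v2.0. The files do not pair contigs with gene names. The 42 gene lists fixed before the data were examined matched 0 contigs and could not be tested. For unnamed probes the fixed rule allows at most 2 identifiers that rose and 2 that fell. Those given have the largest changes at 48 hpi against mock among contigs past the threshold whose arrays did not overlap, and taking them from that comparison was decided after values had been seen. That order is by measured differences of the processed signal, which for TC32897, TC27764 and in part TC21086 rest on values below background.

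To describe groups of contigs, the 60-base probes were translated in 3 frames and searched for short protein motifs of 27 families. The motifs were written after the annotation was found empty and before any expression test. An error that let a motif run across frames was corrected after family results had been seen, and it removed families from the test. A later correction, also made after family results had been seen, ended each peptide at a stop codon and removed 3 contigs with RING or U-box motifs. A family was tested where at least 5 contigs were tested and 20 base-shuffled versions of the probes gave on average under 20% of its hits, which held for 6 families and not for 21. Families were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all on values with marked spots kept because these need complete values.

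The fit was tested on simulated arrays with the real contig means and limma's fitted spreads. There were 10 draws with 200 of 25971 contigs changed. Noise was drawn independently and with the same spread on every array. Changes of 4-fold were called in 58.1% of changed contigs for 24 hpi against mock, 42.4% for 48 hpi against mock and 35.1% for 48 hpi against 24 hpi. Changes of 8-fold were called in 85.5%, 82.4% and 83.8%, and changes of 2-fold in 1.34%, 0.597% and 1.34%. Changed contigs left untested by the rule of 2 unmarked arrays counted as not called, so these rates lie below those for tested contigs. False calls made up 4.95%, 6.72% and 6.5% of all calls. The simulation left out differences in noise between the real arrays, scan session and slide row, and few contigs changed in it. A false share near the threshold was therefore built in, and these rates need not hold for the real arrays.

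The files give each array's place on the slide and its scan time. Scan session 2 held mock replicates 1 and 2 and 24 hpi replicate 2, and session 1 held the other 5 arrays. Slide row 1 held the mock arrays and 24 hpi replicate 1, and row 2 held the other 4. Alternatives covered normalization, background correction, the filter, probes per contig, the variance model, the groups in the fit, replicate number, slide row and scan session as blocks, scan session 1 or 2 alone, marked spots, array weights, arrays with a poor grid, probe GC content, the deposited value table, and leaving out each array. The normexp background correction added an offset of 50 signal units, above the median processed signal of every array (16.1 to 24.8). Such an offset shrinks log2 changes of dim contigs by construction. Figures were drawn with matplotlib 3.10.9.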

Results

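Leaf transcripts of chickpea, a legume crop, were measured after spraying with spores of *Alternaria brassicae*, a fungus known for leaf spot of brassica crops. Plants sprayed with water and 0.05% Tween-20, a detergent, served as mock controls (n = 3 arrays). Inoculated leaves were taken at 24 hpi (n = 3) and 48 hpi (n = 2). The series title places the study in nonhost resistance, the response of a plant to a microbe that does not normally infect its species. The comparisons ask which transcripts differed from mock at each time and which differed between the times.

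Signal over background differed between arrays of the same group. The share of probes well above background was 61.7%, 64.6% and 59.5% on the mock arrays, 58.8%, 38.8% and 45.7% at 24 hpi, and 44.5% and 61.2% at 48 hpi. The standard deviation of the negative controls was between 0.851 and 1.53 signal units in mock, 1.53, 4.43 and 3.38 at 24 hpi, and 3.78 and 1.25 at 48 hpi. The scanner software marked the spot grid as not good on mock replicate 1 and 24 hpi replicate 2. On the first principal component, which held 50.9% of the variance over 20527 probes, the 48 hpi arrays lay at 96.8 and 89.1. The arrays of scan session 2 lay at -116, -64.1 and -32, and the mock and 24 hpi arrays of session 1 lay between -12.2 and 27.8.

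**Figure D1:**
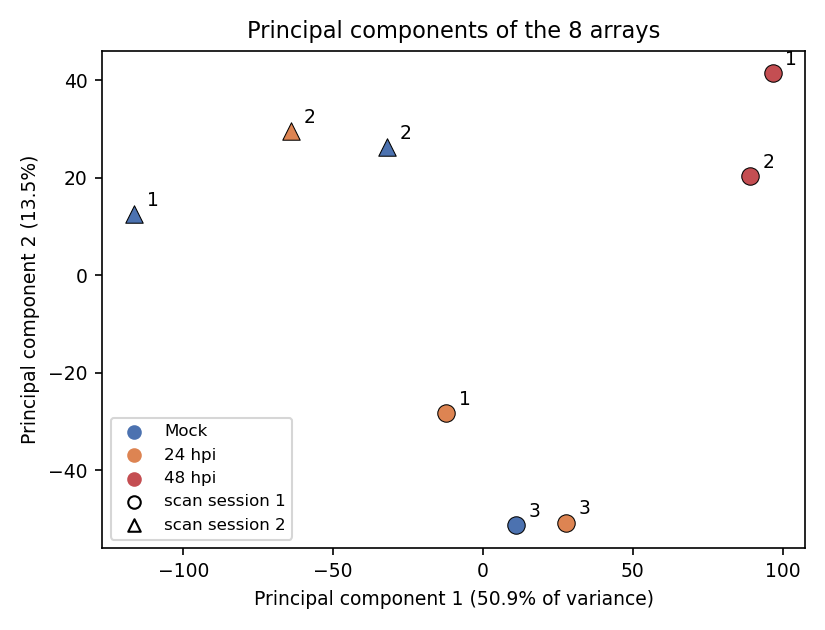
First 2 principal components of the 8 arrays, from log2 signal, with colour for the group, shape for the scan session and the replicate number beside each point. The 48 hpi arrays lie at 96.8 and 89.1 on the first component, and the 3 arrays of scan session 2 lie between -116 and -32.

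At 24 hpi against mock, no transcript passed the threshold. TC21086 stood at -3.28 ± 1.0 (log2, SD, n = 3) against -5.53 ± 1.8 in mock (n = 3), where 1 of 3 arrays was well above background, a difference of 2.24 (SE 0.85, limma adjusted p = 1) that was 0.187 after normexp background correction. TC32897 was well above background on 2 of 3 arrays at 24 hpi and on 0 of 3 in mock, at least 4.25-fold apart on the processed signal (limma adjusted p = 0.91). The mean at 24 hpi includes the array that was not well above background. The log2 difference of TC32897 was 3.88 (SE 1.0). It was 0.845 after normexp, whose offset shrinks changes of dim contigs, and 0.974 with the slide row as a block, both below that bound. TC27764 and TC23278 differed from mock by -0.70 (SE 0.60) and -0.17 (SE 0.51), and neither passed (limma adjusted p = 1 for both). The difference of TC27764 ranged from -1.23 without 24 hpi replicate 3 to -0.131 without 24 hpi replicate 2, and turned to 0.307 within scan session 1. That of TC23278 ranged from -0.394 without mock replicate 2 to 0.182 without 24 hpi replicate 3, and turned to 0.374 with array weights. Contigs with protein kinase motifs, enzymes that phosphorylate proteins and include receptor kinases, had a median difference of -0.04 against 0.08 over all contigs, and 0 of 16 passed. With marked spots kept, the family's median relative to all contigs was -0.172, and it turned to 0.129 without mock replicate 1.

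Other motif families gave 0 contigs past the threshold at 24 hpi as well, also when adjusted over the list alone. These were 6 contigs of NBS-LRR proteins, which are intracellular disease resistance proteins, 11 with motifs of RING or U-box ubiquitin ligases, and 5 each of AP2/ERF transcription factors, leucine-rich repeat proteins and cytochromes P450. For RING and U-box motifs, base-shuffled probes gave on average 2.1 hits against 12 observed. The smallest camera adjusted p among the 6 families was 0.49 (adjusted p = 0.61 with an estimated correlation). It was 0.69 with the scan session as a block. With fry, which does not compare a family with other contigs, the smallest p was 0.095, unadjusted. Within session 1, where mock had 1 array, the AP2/ERF median lay at -0.418 relative to all contigs (camera adjusted p = 0.044), which says little. With the slide row as a block the median of NBS-LRR proteins lay at -0.156 (camera adjusted p = 0.041).

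Of 23345 contigs tested at 24 hpi, 0 passed in limma, with a smallest adjusted p of 0.531. At an unadjusted p under 0.05 there were 965, where chance alone gives 1167. The count was also 0 with the scan session as a block (1211 at an unadjusted p under 0.05) or the slide row as a block (610). Within session 1 (804) and session 2 (1176) it was 0 too, but there mock or 24 hpi had 1 array, so these fits say little. It was 244 with array weights, which gave 24 hpi replicate 1 a weight of 5.58 and 24 hpi replicate 2 a weight of 0.36. It was 1 without 24 hpi replicate 1, namely TC32897 at a log2 change of 5.33 (SE 0.38, limma adjusted p = 0.0046, in a range of 0.0046 to 1 over its alternatives).

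At 48 hpi against mock, 1339 contigs rose and 740 fell among 23360 tested (limma, adjusted p under 0.05). Rises of at least 4-fold were found for 590 contigs and falls of that size for 433. The median log2 change was 1.92 for contigs that rose and -2.16 for those that fell, against 0.23 over all contigs. TC21086 rose from -5.53 ± 1.8 in mock (log2, SD, n = 3) to 1.64 ± 0.76 at 48 hpi (n = 2), a change of 7.17 (SE 0.95, limma adjusted p = 0.014). It was well above background on 1 of 3 mock arrays, so the size of this change rests in part on values below background, and it was 3.12 after normexp background correction. Its probe is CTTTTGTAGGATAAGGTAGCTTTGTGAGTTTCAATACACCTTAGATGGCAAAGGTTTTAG. TC32897, not well above background on any mock array, stood at 0.91 ± 0.27 (log2, SD, n = 2) at 48 hpi and was at least 35.6-fold higher on the processed signal (limma adjusted p = 0.018), a bound that the normexp and slide-row fits, at log2 changes of 2.60 and 2.59, did not reach. Its probe is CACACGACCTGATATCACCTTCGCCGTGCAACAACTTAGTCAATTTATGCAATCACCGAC. TC27764 stood at 1.86 ± 0.58 (log2, SD, n = 3) in mock and was not well above background on either 48 hpi array, at least 45.9-fold lower on the processed signal (limma adjusted p = 0.0064). TC27764 missed that bound after normexp, at -3.48, where the offset shrinks changes of dim contigs. Its probe is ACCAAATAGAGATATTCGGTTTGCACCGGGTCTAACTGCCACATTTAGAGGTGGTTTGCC. TC23278, one of the abundant transcripts at 8.81 ± 0.40 in mock (log2, SD, n = 3), stood at 2.28 ± 1.3 at 48 hpi (n = 2), a change of -6.53 (SE 0.58, limma adjusted p = 0.0064). Its probe is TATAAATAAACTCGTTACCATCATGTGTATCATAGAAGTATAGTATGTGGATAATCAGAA.

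**Figure D2:**
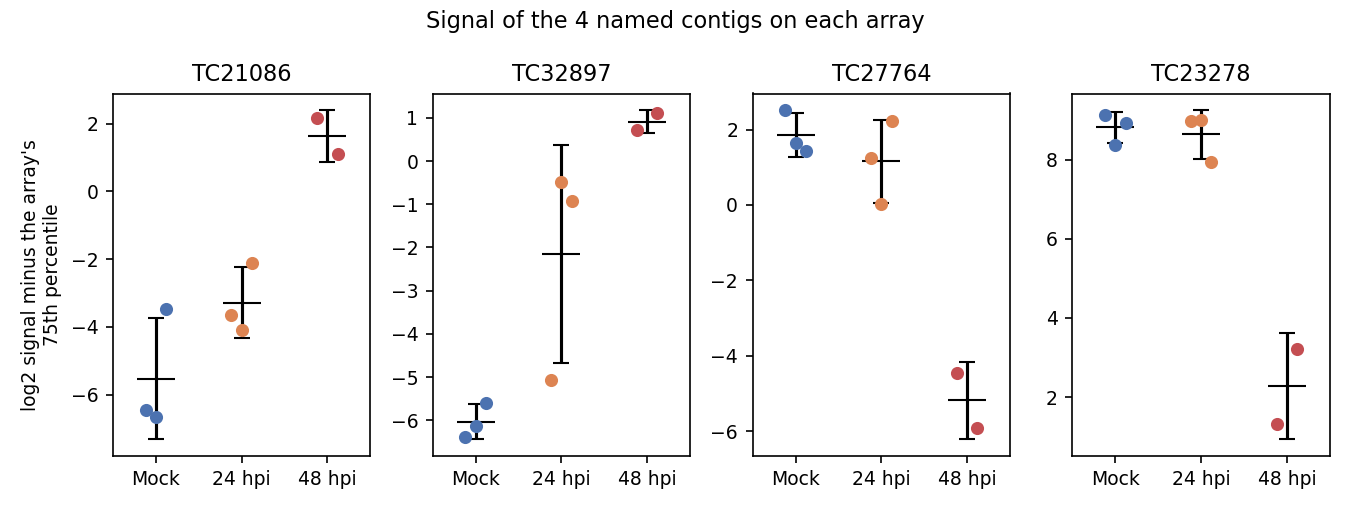
Log2 signal minus each array's 75th percentile for the 4 named contigs, 1 point per array, with the group mean as a bar and the SD as whiskers (n = 3, 3 and 2). TC21086 and TC32897 are highest at 48 hpi, at means of 1.64 and 0.91, and TC27764 and TC23278 are lowest there, at -5.18 and 2.28.

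The changes of these contigs at 48 hpi kept their direction in the scan-session, slide-row and normexp fits, and not always their call or size. Sizes for TC32897 and TC27764, and in part for TC21086, are measured differences from values below background and carry direction rather than size. After normexp the log2 changes were 3.12 for TC21086, 2.60 for TC32897, -3.48 for TC27764 and -6.44 for TC23278, each past the threshold. The normexp offset of 50 shrinks changes of dim contigs, so the smaller values do not test the bounds. With no filter on dim probes the log2 changes were the same as with it, because these contigs kept their values. None passed in that fit (limma adjusted p = 0.096, 0.1, 0.069 and 0.069). With the scan session as a block the log2 changes were 5.73 for TC21086, 7.56 for TC32897, -7.40 for TC27764 and -6.41 for TC23278, and TC32897 no longer passed (limma adjusted p = 0.07, in a range of 0.00048 to 0.2 over its alternatives). Within session 1, where mock had 1 array, they were 5.10, 6.50, -6.60 and -6.65, and none passed (limma adjusted p = 0.11, 0.15, 0.11 and 0.11). With the slide row as a block they were 6.63, 2.59, -6.92 and -6.01, and none passed (limma adjusted p = 0.2, 0.2, 0.13 and 0.13). TC21086 missed the threshold without 48 hpi replicate 1 (limma adjusted p = 0.061). TC32897 missed it without mock replicate 1 (0.052), 48 hpi replicate 1 (0.081) or 48 hpi replicate 2 (0.063). Over all alternatives the adjusted p ranged from 0.00086 to 0.2 for TC21086, 0.00043 to 0.13 for TC27764 and 6.2e-05 to 0.13 for TC23278.

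Many changed contigs at 48 hpi were measured in both groups, and others in 1 group alone. Of the contigs that rose, 45 were well above background on both 48 hpi arrays and on no mock array. Of those that fell, 205 were well above background on every mock array and on neither 48 hpi array. Of all called contigs, 1417 were above background on every array of both groups, 1130 of them higher at 48 hpi and 287 lower. The lowest log2 value well above background was -2.64 and -4.68 on the 48 hpi arrays and -4.12, -4.41 and -4.19 in mock. Of the 100 brightest contigs in mock, 0 rose and 2 fell (limma). Where 2 probes of a contig were tested at different sites, 605 of 5505 contigs had a called probe. In 94.4% of the 605 the 2 probes had the same sign. Both were called in 219 of the 605, and 2 of these had opposite directions.

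Contigs with protein kinase motifs had a median log2 change of -0.98 at 48 hpi, against 0.23 over all contigs, and the family passed with camera at the preset correlation (adjusted p = 0.012) but not with an estimated correlation (adjusted p = 0.27) or with the scan session as a block (adjusted p = 0.096). Of 16 tested, 2 fell, 0 rose and 14 did not pass in limma, and 2 passed when adjusted over the list alone. The members that fell changed by -3.86 (SE 0.53, limma adjusted p = 0.015) and -1.31 (SE 0.34, limma adjusted p = 0.047). Both were well above background on 3 mock arrays and on only 1 array at 48 hpi, so these sizes rest in part on values below background. Several other members were likewise not well above background on every 48 hpi array. Of the 16, 12 were below 0. Relative to all contigs the family's median was -1.35, with -0.793 in the scan-session block (camera adjusted p in a range of 0.0043 to 0.096 over its alternatives), -0.697 within session 1 and -0.93 in the slide-row block. It was -0.857 without mock replicate 1 and -0.608 after normexp (camera adjusted p = 0.036 and 0.031). Of the 16 tested, 14 were dimmer than the median contig, and the normexp offset shrinks changes of dim contigs.

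In the other 5 families at 48 hpi, no contig passed over all contigs tested and no family passed with camera, the smallest adjusted p being 0.29 (adjusted p = 0.43 with an estimated correlation). The median log2 changes were -0.28 for AP2/ERF factors, -0.53 for leucine-rich repeat proteins, -0.47 for NBS-LRR proteins, -0.535 for P450 enzymes and 0.04 for RING and U-box ligases. Adjusted over the list alone, 1 AP2/ERF and 1 NBS-LRR contig fell, and of leucine-rich repeat proteins and of P450 enzymes 1 contig rose and 1 fell. Of RING and U-box ligases none passed. With fry the smallest directional p of these 5 families was 0.073, unadjusted. For changes in either direction fry gave p between 0.0049 and 0.026 for them, and 2.5e-05 for kinases. Fry does not compare with other contigs, and 6824 of all 23360 contigs had an unadjusted p under 0.05. Relative to all contigs, the AP2/ERF median was -0.416 and turned to 0.0364 in the scan-session block. When each array was left out it ranged from -0.662 without 48 hpi replicate 1 to -0.185 without 48 hpi replicate 2. The median of RING and U-box ligases was -0.137 and turned to 0.0615 without mock replicate 1. The P450 median was -0.902, with -0.238 in the scan-session block and -0.425 within session 1, and the family passed in the slide-row block alone, at -1.67 (camera adjusted p = 0.036).

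The count of 2079 contigs past the threshold at 48 hpi depended on the scan session, the slide row, the filter, the scaling and single arrays. With the session as a block 112 passed, 30 of them higher, and within session 1, where mock had 1 array, the count was 0 in limma, with 4697 at an unadjusted p under 0.05. The called contigs had a median change of 1.82 in their direction in both fits against 1.99 before, on arrays that had also chosen them. Within session 1 simulated unchanged groups kept 1.02 of their change for that reason, so the 1.82 there does not test the calls. With the session as a block, 2077 of the called contigs had an unadjusted p under 0.05. With the slide row as a block the count was 0 in limma, with 3179 at an unadjusted p under 0.05. No within-row value exists because mock and 48 hpi arrays lay in different rows. In that fit the called contigs had a median change of 2.07 in their direction against 1.99 before, with a median SE of 0.727 against 0.422, and 1501 of the 2079 had an unadjusted p under 0.05. The count was 0 in limma with no filter on dim probes (6629 at an unadjusted p under 0.05), 896 with quantile normalization and 6046 with array weights. Without the filter the called contigs kept the same values, so their median change of 1.99 could not move. Of them, 2079 had an unadjusted p under 0.05, with a median SE of 0.46. With quantile normalization their median change was also 1.99, with 2069 at an unadjusted p under 0.05 and a median SE of 0.444. The count was 58 without 48 hpi replicate 1, 158 without 48 hpi replicate 2, and 284, 1166 and 1176 without mock replicates 1, 2 and 3. The share of calls that rose was 64.4%, with 79.6% after normexp background correction and 46.6% with the trend on probe GC content removed. Normexp and the removed GC trend moved the median of all contigs from 0.23 to 0.097 and 0.012. Without 48 hpi replicate 1 the share that rose was 15.5%, and without 48 hpi replicate 2 it was 42.4%.

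Between 24 and 48 hpi, 469 contigs rose and 394 fell among 24114 tested (limma, adjusted p under 0.05), by at least 4-fold for 261 and 284. TC23278 changed by -6.36 (SE 0.58, limma adjusted p = 0.0096), from 8.64 ± 0.61 (log2, SD, n = 3) at 24 hpi. TC27764 was well above background on all 3 arrays at 24 hpi and at least 28.2-fold lower at 48 hpi on the processed signal (limma adjusted p = 0.011), a bound that normexp, at a log2 change of -2.96, did not reach. TC21086 rose by 4.93 (SE 0.95, limma adjusted p = 0.036). TC32897 differed by 3.07 (SE 1.1) and did not pass (limma adjusted p = 0.13). Over its 24 alternatives the difference ranged from 1.62 to 5.32, and it passed in 2 of them. Of 17 contigs with protein kinase motifs 2 fell, 0 rose and 15 did not pass, and 3 passed when adjusted over the list alone. Their median was -0.52 against 0.15 over all contigs (camera adjusted p = 0.024, adjusted p = 0.34 with an estimated correlation).

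After normexp the log2 changes between the times were -6.09 for TC23278, -2.96 for TC27764 and 2.93 for TC21086, each past the threshold, and TC32897 passed at 1.75 (limma adjusted p = 0.034, in a range of 0.01 to 0.36 over its alternatives). With no filter on dim probes their log2 changes were the same as with it, and none of the 4 passed (limma adjusted p = 0.1, 0.1, 0.17 and 0.33). The scan-session block gave log2 changes of -6.30 for TC23278, -6.52 for TC27764 and 4.21 for TC21086, each past the threshold (limma adjusted p = 0.028, 0.028 and 0.047). Within session 1 they were -6.18, -6.91 and 4.52, and none passed (limma adjusted p = 0.065 for each). With the slide row as a block they were -6.19, -6.30 and 4.75, and TC21086 did not pass (limma adjusted p = 0.069, in a range of 0.0014 to 0.21 over its alternatives). Between the times the row block amounts to leaving out 24 hpi replicate 1, where TC21086 likewise missed the threshold (0.067). TC21086 also missed it without 24 hpi replicate 2 or 3 (0.071 and 0.06) and without 48 hpi replicate 1 or 2 (0.21 and 0.084). TC27764 missed it without 48 hpi replicate 1 (0.05). The kinase family lay at -0.601 relative to all contigs. It did not pass in the scan-session block (-0.376, camera adjusted p = 0.086) or with quantile normalization (-0.484, camera adjusted p = 0.064). Nor did it pass with normexp (-0.388, 0.055) or without 48 hpi replicate 1 (-0.574, 0.091). It passed in the other 11 alternatives, among them the slide-row block (-0.566, camera adjusted p = 0.03) and the replicate block (-1.07, 0.016). Without 24 hpi replicate 3 its median was -0.935 (camera adjusted p = 0.015). Within session 1, which held 24 hpi replicates 1 and 3 and both 48 hpi arrays, it was -0.503.

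Of the 5 other families, 0 contigs passed between 24 and 48 hpi. With fry their smallest directional p was 0.056, for P450 enzymes, unadjusted. For changes in either direction the smallest fry p was 0.0017, for leucine-rich repeat proteins. Adjusted over the list alone, 3 of 5 leucine-rich repeat contigs fell and 1 rose, 1 of 5 AP2/ERF and 1 of 6 P450 contigs fell, and 0 of 7 NBS-LRR and 0 of 12 RING and U-box contigs passed. The smallest camera adjusted p was 0.085, for P450 enzymes at a median of -0.811 relative to all contigs (adjusted p = 0.35 with an estimated correlation). It was 0.36 in the scan-session block and 0.03 in the slide-row block, which for this comparison is the same as leaving out 24 hpi replicate 1. Within session 1, which held 24 hpi replicates 1 and 3 and both 48 hpi arrays, the median was -0.742.

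Lists of contigs changed at 48 hpi against mock and against 24 hpi overlapped. Of 23100 contigs tested in both, 413 rose in both and 307 fell in both, where independent lists share 26.6 and 12, and 0 went in opposite directions. Both comparisons share the 48 hpi arrays, and simulated unchanged groups against shared arrays gave overlaps of 203 and 125 between lists of the same lengths. The covariance of the log2 changes was 0.863 against 0.125 in the simulation. Part of the overlap may come from the shared arrays, which could not be divided into groups of at least 2. With the scan session as a block the count of 863 between the times became 390, 43.3% of them higher, with the slide row as a block it was 130, and within session 1 it was 0 in limma with 5638 at an unadjusted p under 0.05. It was 3 without 48 hpi replicate 1, 33 without 48 hpi replicate 2, 146, 282 and 29 without 24 hpi replicates 1, 2 and 3, and 1670, 510 and 256 without mock replicates 1, 2 and 3. The share that rose was 54.3%, with 42.6% after quantile normalization, 72.7% after normexp and 67.2% with the GC trend removed. It was 39.7%, 37.2% and 34.5% without 24 hpi replicates 1, 2 and 3, 0% and 12.1% without 48 hpi replicates 1 and 2, and 61.9%, 47.8% and 42.2% without mock replicates 1, 2 and 3.

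Changes at 24 and 48 hpi against the same mock arrays shared 0 called contigs (limma, with 965 and 6824 at an unadjusted p under 0.05 and 137 shared calls with array weights). Across 23100 contigs, which are not independent replicates, the log2 changes had a Pearson correlation of 0.418 and a Spearman correlation of 0.342, and simulated unchanged groups against shared controls gave a Pearson correlation of 0.446. The covariance was 0.2 against 0.0827 in the simulation. Part of the excess may come from the shared mock arrays, which could not be divided into groups of at least 2. The mock arrays' own variance alone gives a covariance of 0.1. The simulation leaves out differences between scan sessions, which held unequal shares of the groups. Of all contigs, 65.6% had the same sign at both times, against 64.7% in the simulation.

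**Figure D3:**
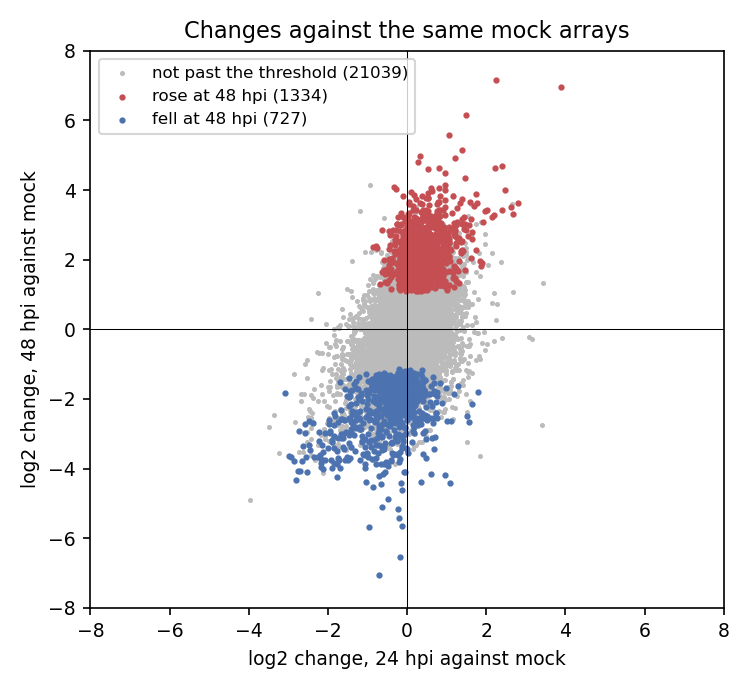
Log2 change at 48 hpi (vertical) against that at 24 hpi (horizontal), both against the same mock arrays, 1 point per contig tested in both, with contigs past the threshold at 48 hpi coloured by direction. Of all contigs, 65.6% have the same sign on both axes, which share the mock arrays, against 64.7% for simulated unchanged groups.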

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

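The tests of probe GC content against the size of the changes, of the slide row as the whole explanation, and on arrays that did not choose the contigs were chosen only after the result was seen, as were the fits with the scan session as a block, within scan session 1 and with the GC trend removed.

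The change from mock differed between 24 and 48 hpi in 863 contigs, by the test of 48 hpi against 24 hpi (limma, adjusted p under 0.05). Among them, TC21086 differed by 4.93, TC27764 by -6.34 and TC23278 by -6.36 log2 units. TC27764 was not well above background on either 48 hpi array, so its size rests on values below background. It is given as at least 28.2-fold on the processed signal, which is not a strict limit. Its log2 change was -2.96 after normexp, whose offset shrinks changes of dim contigs. The count was 390 with the scan session as a block, 0 within session 1 (5638 at an unadjusted p under 0.05), 3 and 33 without 48 hpi replicates 1 and 2, 146, 282 and 29 without 24 hpi replicates 1, 2 and 3, and 1670, 510 and 256 without mock replicates 1, 2 and 3. TC21086 did not pass without any 1 of the 24 or 48 hpi arrays (limma adjusted p between 0.06 and 0.21), and TC27764 did not pass without 48 hpi replicate 1 (0.05).

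The 2079 contigs called at 48 hpi against mock (58 and 158 without 48 hpi replicates 1 and 2, and 284, 1166 and 1176 without mock replicates 1, 2 and 3) were weighed against scan session, slide row and probe GC content. Within session 1 the called contigs kept 0.917 of their median change, but simulated unchanged groups gave 1.02 because the same arrays chose the contigs. The session alone as the whole explanation is argued against only by 2079 contigs chosen without mock replicate 3 and 1 array at 48 hpi. On those arrays they kept 0.649 and 0.564 of the change that chose them (93.5% and 93.9% in its direction). Of the calls, 67.9% had the sign of session 1 minus session 2 in the 24 hpi group. That lies above the bound set in advance as counting for a part played by the session. The difference rests on 1 array, 24 hpi replicate 2, whose spot grid was also marked as not good. Session and grid are not separated there, so the size of such a part stays open. Within row 2 the called contigs differed between 48 and 24 hpi by 0.858 of their change from mock, where sharing the 48 hpi arrays alone gave 0.619 in simulation. The ratio was 0.934 against 24 hpi replicate 2, of session 2, and 0.763 against replicate 3, of session 1 like the 48 hpi arrays. The row alone as the whole explanation is argued against by 2079 contigs chosen with 1 array at 48 hpi. On the other array they kept 0.728 and 0.626 (92.4% and 94.9% in the chosen direction), while the 58 and 155 called with 1 array kept 0.274 and 0.573. Neither test can weigh row and session acting together. The row test included 24 hpi replicate 2 of the other session, and the session test set arrays of different rows against each other. A part played by the row cannot be told apart from inoculation. In the 24 hpi group 42% of calls had the sign of row 2 minus row 1, below the bound set in advance as counting against the row. That bound was judged wrong after the 42% had been seen, because the difference rests on the 1 array of that group in row 1. The 67.9% for the session has the same limit, since it too rests on 1 array. The row block against mock also rests on the 1 array of the 24 hpi group in row 1. It gave a median of 2.07, widened the median SE from 0.422 to 0.727 and ended the calls (0 in limma, 1501 of the 2079 at an unadjusted p under 0.05). With the GC trend removed, the share of calls kept was 0.467 and their median change was 0.975 of that before (1.94 against 1.99, with a median SE of 0.46 against 0.422), and 2060 stayed at an unadjusted p under 0.05, which argues against GC content as the source of the sizes and leaves inoculation open.

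The 10 splits of the 6 arrays of mock and 24 hpi are too few for a share under 0.05, and with 0 calls in the real split (limma, 965 at an unadjusted p under 0.05) each of the 10 had to give at least as many, so they do not test that count. The highest of the others was 1. That split put mock replicates 1 and 2 and 24 hpi replicate 2, the arrays of scan session 2, against the rest. Its 4608 contigs at an unadjusted p under 0.05 point to a structure of the samples along this split. Both arrays with a grid not marked good are in session 2, so the split cannot separate session from grid. With the session as a block the count at 24 hpi was 0 (limma, 1211 at an unadjusted p under 0.05), and the fits within a session have 1 array in mock or at 24 hpi and say little. In simulated arrays with equal noise, 58.1% of 4-fold changes were called, with untested contigs counted as not called. That lies between the bounds set in advance and leaves open whether such changes were few or were missed. Of 2-fold changes 1.34% were called.

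A signal appeared in probes that the comparisons did not use: in 1077 contigs the dimmer probe, of the strand opposite to the brighter one at the same site, also passed the background filter. That was 24.2% of the 4445 contigs whose brighter probe passed, with a median log2 gap of 3.23. Binding of labelled RNA or DNA of the brighter strand could give such a signal and would follow its changes. Across 797 contigs tested on both strands the changes at 48 hpi had a Spearman correlation of 0.37, against at most 0.14 in 200 shuffles, between the bounds set in advance, so the source stays open. No biological explanation was tested.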

How the results depend on the processing

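The fits by scan session, with marked spots kept, with array weights, without the arrays with a poor grid, with 1 unmarked array enough and with the GC trend removed were chosen only after the data were seen. Where no reason is given, the cause was not tested.

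At 24 hpi against mock the count of 0 (limma, 965 at an unadjusted p under 0.05) moved to 244 with array weights and ranged from 0 to 1 when each array was left out. At 48 hpi against mock (2079) it was 896 with quantile normalization, 3361 with trend and robust eBayes, 112 with the scan session as a block, 680 with marked spots kept, 6046 with array weights, 1248 without the 2 arrays with a poor grid and 994 with the GC trend removed. It was 0 in limma with no filter on dim probes (6629 at an unadjusted p under 0.05), with the slide row as a block (3179) and within session 1 (4697), and ranged from 58 to 3012 when each array was left out. Without the filter 36622 contigs were tested instead of 23360. The prior degrees of freedom of the limma fit, which set how strongly contigs share their spread, were 2.74 against 4.27. The median SE of the called contigs was 0.46 against 0.422. Within session 1 fewer arrays were used. Which of these ended the calls was not tested. Normexp (2933), the filter on all 8 arrays (2471), every probe on its own (2440), the 2 groups alone (2284), the deposited values (2086) and 1 unmarked array enough (2041) stayed within 1.5 times.

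At 48 hpi against 24 hpi (863) the count was 312 with quantile normalization, 2039 with normexp, 1698 with the filter on all 8 arrays, 2175 with trend and robust eBayes, 487 with the 2 groups alone, 130 with the slide row and 390 with the scan session as a block, 102 with marked spots kept, 5645 with array weights and 476 with the GC trend removed. It was 0 in limma with no filter (5238 at an unadjusted p under 0.05) and within session 1 (5638), and ranged from 3 to 1670 when each array was left out. Shared calls of 24 and 48 hpi moved from 0 to 137 with array weights and ranged from 0 to 1 when each array was left out.

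With the replicate block, 987 contigs passed at 48 hpi against mock and 0 at 48 hpi against 24 hpi (limma, 6936 at an unadjusted p under 0.05). Deviations of same-numbered mock and 24 hpi arrays correlated at 0.018, 0.093 and 0.58, which does not pair them, and mock replicate 1 correlated best with 24 hpi replicate 2 (0.4).

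Of 295 alternative values of the 4 named contigs, 250 kept direction and side of the threshold, 36 lost the call, 3 gained it and 6 reversed. All 6 were at 24 hpi, where neither contig passed. TC27764 turned to 0.307 within session 1 and 0.198 without the arrays with a poor grid. TC23278 turned to 0.172 with the slide row as a block, 0.251 within session 2 and 0.374 with array weights, and ranged from -0.394 to 0.182 when each array was left out. The fixed gene lists gave no values to vary. Arrays with low signal over background, 24 hpi replicates 2 and 3 and 48 hpi replicate 1, limit what can be seen of dim contigs.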

Other observations

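The tests of motif families were chosen after the probe annotation was found empty, and the search was corrected more than once after family results had been seen.

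Contigs of families with too few members or too many chance hits to test also held values, and of 25 such contigs 4 rose at 48 hpi against mock and 21 did not pass. Of 4 contigs with MYB transcription factor motifs, 1 rose, by 2.37 log2 units (SE 0.44, limma adjusted p = 0.025). A contig with a motif of papain-like proteases rose by 3.03 (SE 0.75, limma adjusted p = 0.041), in a family with 2 contigs against 0.3 on average in base-shuffled probes. The other 2 that rose matched motifs of class III peroxidases and of chaperones, families with 2 and 1 contigs against 0.45 and 0.55 in shuffled probes, above the 20% limit, so these names are not reliable. A contig with a motif of WRKY factors, known for roles in defence, differed by -0.04 (SE 0.35, limma adjusted p = 0.96). Of the 2 naming series on the array, 8.84% of tested TC contigs and 9.26% of tested Ca_MJ contigs changed (Fisher's exact test across contigs, p = 0.44).

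It was predicted as a hypothesis that contigs with receptor-type motifs of defence, protein kinases or NBS-LRR proteins, lie higher at 48 hpi than other contigs. The test went against it: the lower camera p of these families with an estimated correlation was 0.046, for kinases, and its direction was down, while NBS-LRR proteins had a p of 0.25, also down. Adjusted over the 6 families the kinase p was 0.27 with an estimated correlation, and with the scan session as a block camera at the preset correlation gave an adjusted p of 0.096 (range over alternatives 0.0043 to 0.096). The median of the kinase contigs was as low in 0.01% of 10000 random lists matched on mock level, which leave out correlation between members. Of the 16, the 14 dimmer than the median contig had a median of -1.09 against 0.125 for all dimmer contigs, and the 2 brighter had -0.16 against 0.30. Several of the 16 were not well above background on every 48 hpi array, so their sizes rest in part on values below background.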
